A study of Drosophila melanogaster with 3 samples.

How the data were processed

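The series is a chromatin immunoprecipitation sequencing (ChIP-seq) study of Myc, the Drosophila member of the Myc family of growth-promoting transcription factors, in Kc167 cells. Kc167 is an established Drosophila melanogaster line of embryonic origin, labelled female. Per the labels, 2 ChIP samples and 1 input sample (sheared chromatin without immunoprecipitation) were sequenced. Per the labels' protocols, cells were fixed in 1.8% formaldehyde for 15 min, and the ChIP used a rabbit polyclonal antibody raised against residues 46 to 507 of the protein. Groups and replicate numbers were taken from the sample titles.

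The measurement analysed is 1 list of peaks for the whole series. Per the file headers, its coordinates are those of FlyBase release 5, and each line names MACS as its source. CASAVA, BWA, MACS2 and the BDGP5 genome build are named in the submitters' processing notes. Each peak carries 1 score with 2 decimals, made by the authors' peak caller and deposited without a statement of its scale, so it was compared only among peaks within this list, and no ratio of scores was read as a fold of enrichment. How reads that map to several places were treated, whether the ChIP libraries were pooled, whether the input set the local background and which threshold was applied are not given in the sources used here. The list holds no value per replicate and no read counts: the depth of each sample is therefore unknown, no interval that needs a depth is given, and no replicate error can be attached to any peak. Intervals on shares below are exact binomial intervals at the 95% level that cover only the counting of peaks, and p-values across peaks treat peaks as units, although neighbouring peaks are not independent replicates.

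From the list, peak widths, covered length, and shares per sequence were computed. The end of the last peak on each sequence stood in for its length, because the list gives no lengths. This end can fall well short of the true length, most of all on sequences with few peaks. It was not checked against true lengths, so whether any peak runs past the end of its sequence is unknown. Each sequence's count of peaks was compared with its share of the summed length by an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the sequences. Mean log10 scores on X and on 2L, 2R, 3L and 3R were compared by a two-sided permutation test with 100000 resamples. The share of peaks with another peak midpoint within 5000 bp was compared with 1000 uniform placements of the same number of peaks on each sequence; the smallest p these can give is 0.002. For this test, permutation p means the two-sided share of such placements. After the list had been examined, peaks closer than 3000 bp were also joined into loci (with 1000 and 5000 bp as alternatives), and the spans of the loci, the position of loci along the arms and a dense run of peaks on 2L were analysed. The rule for named items, set before the data were examined, took the 10 peaks with the highest score by position, and any other peak named was chosen after its values were seen.

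Tests that need gene positions or sequence (start sites, gene lists and motifs at peaks) were not run. The gene table used here follows release 6 of the genome and the peaks follow release 5, so no peak was assigned to a gene; the table served only for gene names and for which genes neighbour each other. Alternatives fixed at the same time as that rule were peaks at or above the median or the upper quartile of score, merging of peaks closer than 500 bp, covered length in place of peak counts, ranks in place of log10 scores, and another placement for spacing.

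The computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and were tested on simulated data. With no effect, 0.02 of the 15 sequences were called per draw on average, and a 1.5-fold excess on Uextra was recovered in 100% of draws of 9897 peaks. At the real numbers of peaks on X and the large autosome arms, a log10 score difference of 0.1 was recovered in 98% of draws and 2% of draws without a difference passed. In simulations of the 810 arm peaks, 5% of uniform placements passed the spacing test. In the simulations behind these rates, peaks were drawn independently of each other. In the list, several peaks can belong to 1 enriched region, so the rates of false calls given here do not carry over to it.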

Results

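To map where Myc binds in Kc167 cells, chromatin from 2 ChIP samples was sequenced beside 1 input sample, and 1 list of 9897 peaks was produced for the series. The peaks covered 5.98 Mb of release 5 sequence. Their median width was 531 bp (interquartile range 381 to 644 bp), the narrowest was 201 bp and the widest 9286 bp. Scores ran from 6.31 to 368.39 with a median of 25.1. Because the list has no values per replicate, none of the values below carries a replicate error, and the depth of each sample is unknown.

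Most Myc peaks lay on sequence that release 5 does not place on a chromosome. Uextra and U, the collections of unplaced scaffolds, held 8939 of the 9897 peaks (90.3%, exact 95% interval 89.7 to 90.9%) and 84.2% of the covered length. Uextra alone held 8233 peaks (83.2%) and U held 706 (7.13%). The 6 chromosome arms held 810 peaks (8.18%, 7.65 to 8.74%), the scaffolds assigned to heterochromatin held 142 (1.43%) and the mitochondrial genome held 6. Measured up to the last peak on each sequence, Uextra had 284 peaks per Mb, U had 70.4, the heterochromatin scaffolds together had 16.2 and the arms together had 6.81.

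Relative to its share of the summed length, Uextra carried 4.79 times the number of peaks expected and U 1.19 times, while the arms together carried 0.115 times the expected number and the heterochromatin scaffolds 0.272 times. Each of the 15 sequences differed from its expected share (exact binomial test, two-sided, adjusted over the 15), the weakest being YHet, with 2 peaks and an adjusted p of 0.0219. The ratios share 1 total, of which Uextra held 83.2%, so its excess lowers the ratio of every other sequence. The 15 calls are therefore not separate results. The 6 mitochondrial peaks were 5.15 times the expected number (exact binomial test, adjusted p = 0.00149). After merging of peaks closer than 500 bp, the calls for the mitochondrial genome (ratio 1.152), XHet and YHet were lost (exact binomial test, adjusted p = 0.580, 0.0675 and 0.112). By covered length in place of peaks, the mitochondrial ratio was 25.8. On the heterochromatin scaffolds, 3LHet and 3RHet had 23.5 and 23.2 peaks per Mb and 2RHet had 7.09. YHet, a set of Y chromosome scaffolds, carried peaks with scores of 19.44 and 63.98 in this line labelled female.

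**Figure D1:**
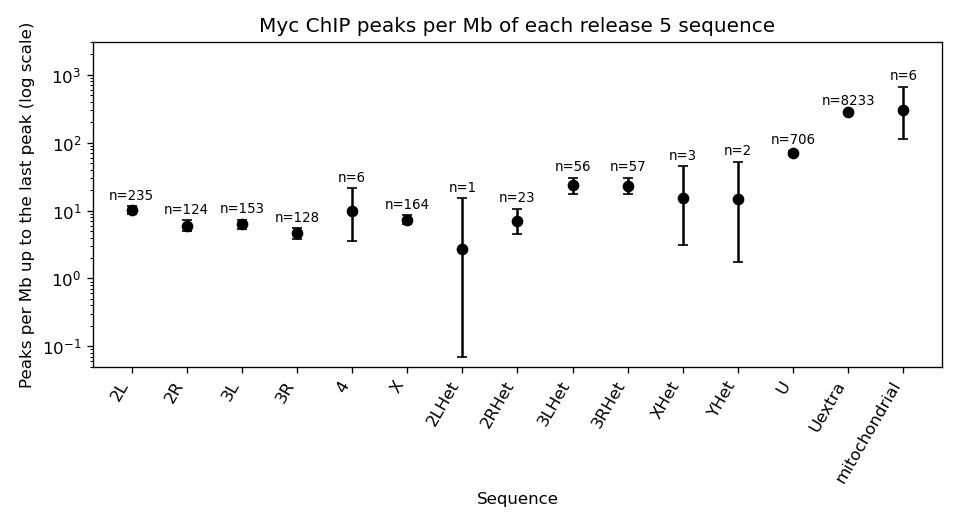
Peaks per Mb (log axis) for each release 5 sequence, counted up to the last peak; points are the counts in the list, bars are exact binomial 95% intervals and n is the number of peaks. Uextra, at 284 peaks per Mb, lies above every chromosome arm; 2L has 10.2, or 6.61 without the dense stretch at 21416419 to 21543476.

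The sequence classes also differed in the size and score of their peaks. Uextra peaks had a median width of 539 bp (interquartile range 404 to 635 bp), a widest peak of 2658 bp and a median score of 26.02. Arm peaks had a lower median width, 403 bp, and a lower median score, 14.025, but 64 of the 77 peaks of 4000 bp or more in the whole list were on the arms and none was on Uextra. The list does not give the ends of the scaffolds collected in U and Uextra, so whether scaffold length limits peak width there was not tested. The heterochromatin scaffolds had a median width of 321 bp and a median score of 13.4.

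None of the 10 highest scores was on a chromosome arm. The top peak covered positions 16626 to 19614 of the mitochondrial genome with a score of 368.39, and the peak at 12068 to 15636 of the same genome scored 188.6. The other mitochondrial peaks scored between 28.45 and 97.5. All 6 together covered 18287 bp of the 19614 bp up to the end of the last, so they do not mark separate sites. Whether they reflect Myc binding was not tested. On U, the highest score was 191.45, at 5298935 to 5303504, followed by 139.59 at 2605833 to 2606299, 132.31 at 2293397 to 2293953 and 129.76 at 5288436 to 5290168. On Uextra, the highest was 148.57, at 28348932 to 28349408, followed by 140.54 at 26418802 to 26419546, 138.41 at 18613632 to 18614847 and 134.41 at 4753290 to 4754329. The highest score on an arm, named here after its value was seen, was 102.31 for the last peak on X, at 22422284 to 22422903. A peak of nearly equal width and score opened XHet, at 57 to 742, with a width of 686 bp against 620 bp and a score of 96.96.

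Among the arms, 2L held more peaks and 3R fewer than their lengths predict. 2L had 235 of the 810 arm peaks, 1.499 times the expected number (exact binomial test adjusted over the 6 arms, p = 2.17e-10), and 3R had 128, 0.675 times (adjusted p = 3.70e-07). The ratios for 2R, 3L, 4 and X lay between 0.882 and 1.43 with adjusted p of 0.275 or more. The excess on 2L came from 1 stretch: positions 21416419 to 21543476, a span of 127 kb, held 83 of the 235 peaks on 2L and was covered to 74.0% by them. This comparison among arms, and the one without the stretch, were chosen after the list had been examined. Without it the ratio for 2L was 1.08 (exact binomial test, adjusted p = 0.452), that for 3R was 0.752 (adjusted p = 0.000968) and that for X was 1.20 (adjusted p = 0.0359).

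Joining peaks closer than 3000 bp gave 336 loci on the arms, a unit chosen after the list had been examined. X had 84 loci, or 3.75 per Mb, 1.33 times the expected number (exact binomial test, adjusted p = 0.0312). 2L had 64 loci (2.78 per Mb), 2R 55 (2.67), 3L 69 (2.83) and 3R 60 (2.16). Counted up to its last peak, which ended at 616211, arm 4 had the highest density, 6.49 per Mb, from only 4 loci. A longer true length would lower this density, so its rank among the arms is not settled. Its count was 2.30 times the expected number (exact binomial test, adjusted p = 0.198), a ratio with the same limit. The deficit on 3R, at 0.763 times the expected number, missed the threshold in the same test with an adjusted p of 0.0508. It passed with peaks joined under 1000 bp (0.759 times, adjusted p = 0.0426 in the exact binomial test) and not under 5000 bp (0.775 times, adjusted p = 0.0773). The call for X was lost without the 2 Mb at the end of each arm except 4 towards the centromere, where the ratio was 1.21 (exact binomial test, adjusted p = 0.219). In the same setting 3R had 0.825 times the expected number of loci, also short of the threshold (exact binomial test, adjusted p = 0.219).

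**Figure D2:**
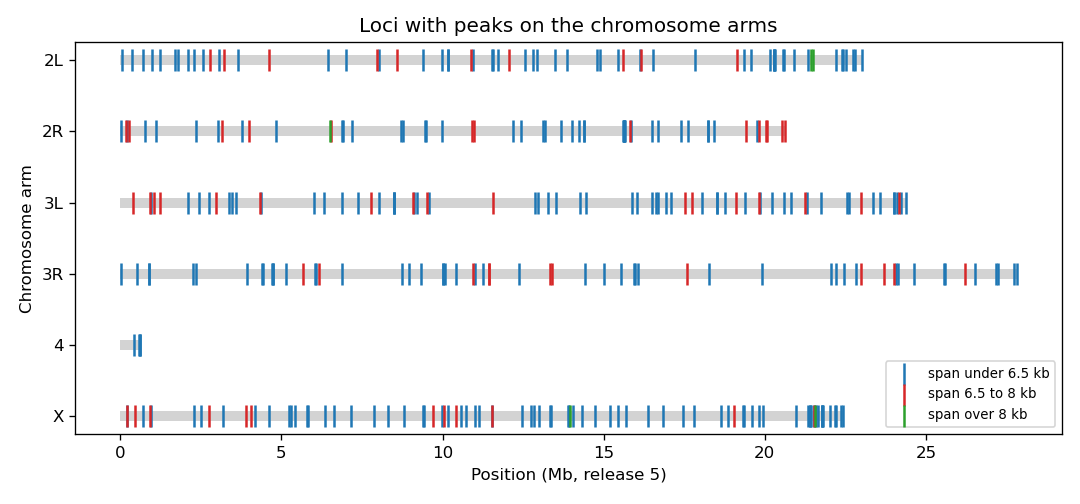
Loci with peaks (vertical ticks, joined at 3000 bp) along the chromosome arms, by position in Mb; grey bars end at the last peak, and colour gives the span of the locus. Of the 84 loci on X, 19 lie in the 2 Mb at its right end, and the 65 loci of 6.5 to 8 kb are spread over 5 arms.

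Peaks on X also scored higher than peaks on the large autosome arms. The median score was 18.8 (interquartile range 11.5 to 34.6) for the 164 peaks on X and 13.5 (10.0 to 25.7) for the 640 peaks on 2L, 2R, 3L and 3R. The mean log10 score was 1.32 ± 0.298 (SD across peaks) on X and 1.21 ± 0.266 on the autosome arms, a difference of 0.108 (permutation test across peaks, two-sided, p = 4.0e-05). With loci in place of peaks, the difference was 0.109 over 84 and 248 loci (permutation p = 0.00718). Because the scale of the score is not stated, only the direction of this difference can be read. These tests compare peaks within 1 list and do not measure the spread between ChIP samples. Whether the difference depends on the 2 Mb next to the centromere, without which the call for more loci on X was lost, was not tested.

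Arm peaks, taken apart from the other sequences after the list had been examined, were clustered. Of the 810 arm peaks, 625 (77.2%) had another peak within 5000 bp, against 7.02% on average in uniform placements, and none of the 1000 placements reached the observed share (two-sided permutation p = 0.002, the smallest these can give). The share was 89.8% on 2L, 77.4% on 2R, 75.2% on 3L, 69.5% on 3R and 65.9% on X, and it was 74.6% on the arms without the dense stretch of 2L. After merging of peaks closer than 500 bp, the share on the arms fell to 46.4% (222 of 478), 11.1 times that in uniform placements, and among scores at or above the median it was 64.8% (151 of 233), 30.5 times. Neighbouring peaks can be pieces of 1 enriched region. With peaks joined under 3000 bp, the 810 arm peaks formed 336 loci. The 42 loci of several peaks that spanned 6.5 to 8 kb and scored 30 or more held a median of 4 peaks. The spacing of loci was not tested, so these shares do not show that separate sites are clustered. With placement within 1 Mb blocks, added after the list had been examined, the expected share on the arms was 15.6%. With the observed gaps shuffled within such blocks, it was 80.7%, above the observed share (permutation p = 0.002), a placement that keeps every gap and tests only their order. On U, 79.0% of peaks had such a neighbour against 50.5% in uniform placements. On Uextra, where peaks are dense enough that most have a neighbour by chance, the share was 94.9% against 94.2%. Positions on U and Uextra run across the ends of unplaced scaffolds, so neighbours there need not be neighbours in the genome. Over all sequences, the share was 92.1% against 82.8% (permutation p = 0.002).

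Within the dense stretch of 2L, a repeat of the peak pattern was tested after the stretch had been seen. The autocorrelation of covered bases over lags of 3000 to 8000 bp was highest at 5040 bp, where it reached 0.309, against a median of 0.174 and a 95th percentile of 0.229 for the highest value when peaks and gaps were shuffled (1000 shuffles, one-sided permutation p = 0.001, the smallest these can give). The median score in the stretch was 20.2 and the highest was 37.68.

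**Figure D3:**
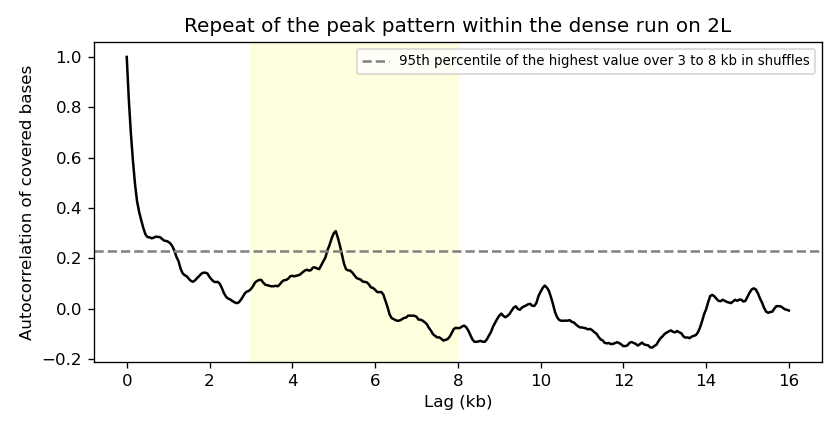
Autocorrelation of the bases covered by peaks within 2L 21416419 to 21543476 against lag in kb; the shaded band marks the lags tested and the dashed line the 95th percentile of shuffled peaks and gaps. The highest value in the band, 0.309, lies at a lag of 5040 bp.

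Loci on the arms were also grouped by span, after their spans had been seen. The 140 loci under 500 bp had a median score of 12.1. At the other end, 65 loci spanned 6.5 to 8 kb, had a median highest score of 49.7 and were found on all arms except 4: 17 on 3L, 14 on 2R, 12 on 3R, 12 on X and 10 on 2L. Of these, 20 were single unbroken peaks with a median width of 6972.5 bp and scores of 57.5 to 80.8, including 2L 12067383 to 12074354 (score 80.83), 3L 7786873 to 7793863 (80.13) and 3R 23701449 to 23708459 (77.55). Single peaks with scores in this range were not limited to that span, since 22 others were 426 to 6221 bp wide. The other 45 were made of several peaks. Of these, 42 had a highest score of 30 or more, a division set after the scores had been seen, with a median total span of 7387.5 bp, peaks over 92.0% of that span and highest scores of 32.1 to 64.9. The remaining 3 had highest scores of 12.2 to 19.4 and peaks over 45.3% of their span.

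**Figure D4:**
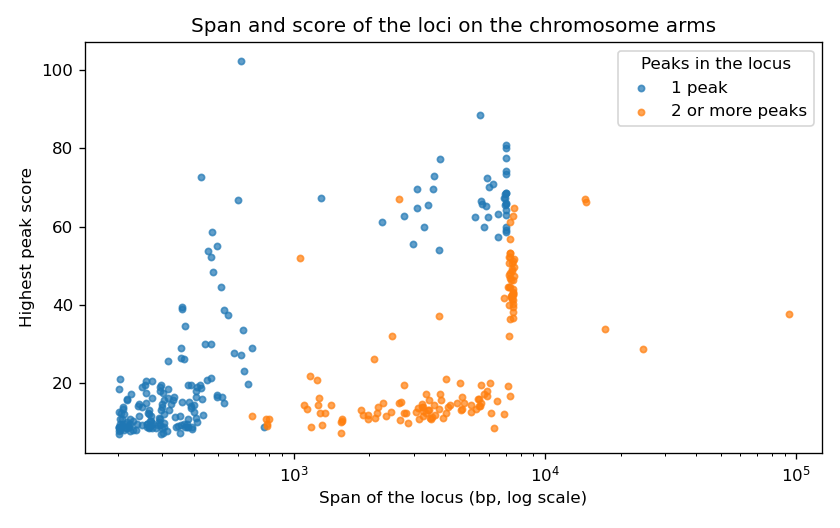
Span in bp (log axis) against the highest peak score for each of the 336 arm loci, with colour giving whether the locus holds 1 peak or several. A column of 20 single-peak loci lies between 6.5 and 8 kb with a median of 6972.5 bp, and 22 single-peak loci within its score range have shorter spans, of 426 to 6221 bp.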

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

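No paired analysis was possible because the list holds 1 value per peak for the whole series; for the same reason no replicate could be left out. Alternatives that need genes, start sites or sequence of release 5 were not run. Each sequence kept its direction against its length under covered length, scores at or above the median, merging at 500 bp and joined loci, the last added after the data were seen: 53 of 60 values also kept their side of the threshold, and the other 7, on XHet, YHet and the mitochondrial genome, lost it. The number of sequences past the threshold was 15 by peaks and 12 to 15 otherwise. For covered length, each sequence's share of covered bases was scaled to the number of peaks and rounded before the test. Its calls therefore rest on scaled values and not on counts of peaks. The share of peaks on U and Uextra moved from 90.3% to 94.6% at scores at or above the median, 93.6% at or above the upper quartile and 92.2% after merging. Under the same settings the median width moved from 531 bp to 612, 641 and 595 bp, and the median score from 25.1 to 33.69, 40.68 and 27.16; the rise in score follows from selecting by score or keeping the highest score of merged peaks, merging widens peaks by construction, and the cause of the greater width at higher scores was not tested. The score difference between X and the autosome arms kept its sign and call in all 4 alternatives, of which loci and the list without the dense 2L stretch were added after the data were seen (0.104 on ranks, 0.109 to 0.134 on log10 scores). Clustering was tested on peaks and not on loci. The ratio of observed to placed neighbours stayed above 1 except when the gaps themselves were shuffled within 1 Mb blocks. It was then 0.996 over all sequences (permutation p = 0.04) and 0.956 on the arms (permutation p = 0.002). That placement keeps every gap and tests only their order, so a ratio below 1 there does not mean that peaks are less clustered. Unknown depth and the lack of a value per replicate limit every result.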

Other observations

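All tests in this part were chosen after the list had been examined. Uextra was not uniform along its coordinate, which runs across the unplaced scaffolds it collects and is not a position on a chromosome. Its first 6 Mb held 142 peaks per Mb with a median width of 737 bp, the stretch from 12 to 18 Mb held 319 per Mb at 556 bp, and the stretch from 18 to 24 Mb held 365 per Mb at 532 bp, while the median score stayed between 24.9 and 27.2 in all 5 parts. Of the loci on 2L, 2R, 3L, 3R and X, 50 of 332 lay in the 2 Mb next to the centromere, against 28.3 on average in 10000 uniform placements. The share of placements with as many gave a one-sided Monte Carlo p of 3.0e-04. X had 19 such loci against 7.49 expected, 3L had 11 against 5.66, 2L had 10 against 5.56, 2R had 6 against 5.33 and 3R had 4 against 4.31. The placements treat loci as independent, so the p does not allow for loci that lie close together. Examples are the loci starting on X at 21406849, 21412901 and 21421814. The dense stretch of 2L also entered as separate loci, starting at 21416419 and 21450248. A pair of longer loci had nearly equal spans, 14495 bp on X at 13940935 to 13955429 and 14582 bp on 2R at 6510024 to 6524605.

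The scores carry information on their own scale. Of the 80 scores shared by at least 15 peaks, 79 lie within 0.015 of −log10 of a Poisson tail, the chance of more than k reads for whole numbers k, at a single background of 27.84. That background was chosen to give the most such matches. On U and Uextra, 76.8% of scores (exact 95% interval 75.9 to 77.7%) lie on this ladder, against 1.35% on a decoy ladder shifted between its steps. On the arms 16.8% do (14.3 to 19.5%, decoy 6.05%). A score on the ladder cannot also lie on the decoy, so the decoy share falls where the ladder share is high and is not a chance rate. If the scores are read this way, the median k at ladder scores on U and Uextra was 99, or 3.56 times the background. The hypothesis is that the score is −log10 p and that 27.84 is the lowest background the caller allowed.

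Why so many peaks fall on U and Uextra was weighed against technical explanations. Splitting of sites into several short peaks beside each other does not account for it. After joining peaks closer than 3000 bp, 88.1% of 3378 loci were still there (86.9 to 89.1%), against 23.4% of the summed length. Joining by coordinate cannot merge pieces or copies of 1 site that lie on separate scaffolds, and it can merge neighbours across scaffold ends. Whether 1 site was counted on several scaffolds was therefore not tested. Repeat copies missing from the assembly would raise ChIP and input alike, and most scores there should then lie off a ladder of 1 common background, whereas 76.8% lie on it. That ladder was fitted to scores mostly from these sequences, and no source states that its background is the lowest or that the input set the local background, so the explanation stays open. DNA of other origin in the ChIP libraries, loss of these sequences from the input and the treatment of reads with several matches were not tested, and the design gives no group that tests a biological explanation.

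The arm loci near 7 kb may be copies of a few repeated elements, such as transposable elements present in the reference arms. Among 137 loci spanning at least 3000 bp, 17 fell between 7427 and 7516 bp, the densest window of 100 bp, against a median of 9 and a 95th percentile of 12 when spans were resampled and smoothed by 10% in 10000 draws, a one-sided Monte Carlo p of 2.0e-04. The 3000 bp joining distance does not account for this window, which also held 17 loci with peaks joined under 1000 or 5000 bp; under 500 bp, the densest window was instead 6907 to 7004 bp, with 15 loci. Those 15 loci are single deposited peaks. Tested among single peaks, the same 15 widths compared with a 95th percentile of 9, with a Monte Carlo p of 0.0001, the smallest these draws can give. This is the same observation and not further support. Without sequence the elements were not identified, and whether the enrichment over them reflects Myc, copy number that differs from the input or the placement of multiply matching reads remains open, and no biological explanation was tested.

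The dense stretch on 2L is a candidate tandem array, since its autocorrelation of 0.309 at a lag of 5040 bp exceeded the shuffled 95th percentile of 0.229. A candidate source is the replication-dependent histone gene cluster, which lies on 2L: the release 6 gene table lists 23 copies of His1, 23 of His2B, 23 of His3, 22 of His4 and 20 of His2A there, within 119 histone genes and pseudogenes interrupted by 20 other genes. Release 6 positions were not carried over to release 5, so the overlap itself was not tested, and reads that match many repeat units stay an open technical source of the peaks.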
